A study of Mus musculus with 10 samples.

How the data were processed

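The samples were B16-F10 mouse melanoma cells (WT) and B16-F10-OVA cells, untreated or given IFN-γ for 24 h at 50 ng/ml, with 2 untreated and 3 treated libraries of each line. The extraction protocol speaks of tissue while the other labels name cell lines, and the samples are taken as cell lines here. The labels describe poly-A selected RNA libraries and do not say that they are stranded, so genes that overlap on opposite strands are uncertain. The deposited table holds raw read counts per Ensembl gene for the 10 samples. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.6.0 and the GRCm39 build. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here, so values of paralogs and pseudogenes are uncertain. No coordinates are printed, because the table gives none and the reference used here is of another build.

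The table had 77175 entries, of which 21805 had no symbol and 39963 had no counts in any sample. Total counts per library ran from 17728722 to 19642533. Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, two-sided, TMM factors, the low count filter filterByExpr on group), with p adjusted by Benjamini-Hochberg over the 15526 tested genes at a threshold of 0.05. All 10 samples were fitted together with the 4 groups as means, so that groups of 2 share the estimate of the spread. The 5 comparisons were IFN-γ against untreated in each line, the difference of those responses (OVA minus WT), and OVA against WT untreated and treated. The labels do not say that replicates are separate cultures, so the p-values measure the spread between these samples, which can be technical. Levels are CPM with TMM factors, given as mean ± SD.

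A gene with no counts in a group is given as at least N-fold against a floor of 3 counts summed over the group, and a gene with 1 to 3 counts as a ratio with its 95% counting interval. Intervals and floors cover counting error only. The score is the mean log2 CPM (prior count 2) of the tested class I, GTPase and antiviral genes, compared with exact two-sided permutation tests.

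Before the data were examined, 25 gene lists, the comparisons, the score, the rule for naming genes and the alternatives were fixed. The lists covered class I and class II antigen presentation, receptor and JAK-STAT signalling, GTPases, antiviral genes, chemokines, checkpoint ligands, adhesion, melanocyte differentiation, dedifferentiation, cell cycle, p53 targets, cell death, complement, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis, stress, hypoxia, early response, and markers of T, macrophage, fibroblast and epithelial cells. They were tested with camera in limma 3.58.1 (preset correlation 0.01, 125 tests adjusted together), and again with an estimated correlation and with fry. Members that did not pass the count filter were not tested. Shares and medians cover tested members only, and so leave out genes that stayed low in all groups. Tested were 15 of 24 chemokine, 15 of 27 checkpoint, 8 of 13 complement, 10 of 19 dedifferentiation and 12 of 15 class II members. Named genes were (a) 22 fixed genes, of which Icam1 was too low to be tested and 1 is not reported here, (b) per comparison the 10 largest increases and 10 largest decreases among called genes with a symbol, at least 5 CPM in the higher group and no overlap between the libraries of the groups, an overlap not asked of the difference of responses, and (c) up to 4 called members per list. From (b) and (c) the text gives a part. The hypoxia list holds Car9 under an older symbol that the table lacks, so it was not counted.

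The alternatives were DESeq2 1.42.0 size factors and Wald test, limma-voom, no filter, a stricter filter (1 CPM in 5 samples), a replicate block, only the groups compared, an adjusted p under 0.01, at least 2-fold, other score settings, and each library left out in turn. Protein-coding genes by GENCODE M21 were added as an alternative after seeing the data. The pipeline was tested on simulated data with 50 changed genes per fold among 15526. Each gene otherwise kept its mean over all 10 libraries, so induced genes silent in untreated cells were not simulated. The real WT and OVA comparisons called 6858 and 7580 genes, far more than were changed here. The recovered shares do not carry over to such comparisons. At the smallest simulated fold, 5/4, the pipeline recovered 44% for WT, 54% for OVA and 36% for the difference of responses. It recovered 44% between untreated and 62% between treated lines, so changes of that size can be missed. At 1.5-fold, 2-fold and 4-fold it recovered 60%, 70% and 94% for WT, 76%, 72% and 88% for OVA, 48%, 68% and 80% for the difference of responses, 70%, 66% and 96% between untreated lines and 62%, 82% and 92% between treated lines. It made 8, 8, 8, 13 and 11 false calls in these comparisons. The ovalbumin transgene was not analysed here.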

Results

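Gene expression was measured by bulk RNA sequencing in B16-F10, a mouse melanoma cell line, and in B16-F10-OVA, a derivative carrying a lentiviral vector that expresses ovalbumin, a model antigen. Each line was sampled untreated and after 24 h with interferon gamma (IFN-γ) at 50 ng/ml. The lines are called WT and OVA here. Each line had 2 untreated and 3 treated libraries, 10 in all. The total count per library ran from 17728722 to 19642533. The 10 most abundant genes took 6.07% to 7.18% of the counts of a library. The 1st principal component held 72.9% of the variance, and the 2nd held 6.06%. Of 77175 entries in the table, 15526 had enough counts to be tested. The series asked whether the lines respond differently to IFN-γ.

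In WT cells, IFN-γ raised genes of its own signalling pathway and of antigen presentation. Irf1, a transcription factor of the interferon response, rose by 6.04 log2 units (SE 0.069, adjusted p = 8.01e-22). Its level went from 10.7 ± 0.520 to 701 ± 22.6 CPM (counts scaled to library size, mean ± SD, n = 2 and 3). The class I heavy chain genes H2-K1 (ENSMUSG00000061232) and H2-D1 rose by 4.75 (SE 0.049) and 3.92 (SE 0.043), and the light chain gene B2m rose by 3.82 (SE 0.033). Tap1, a subunit of the peptide transporter, rose by 8.36 (SE 0.17). The immunoproteasome gene Psmb8 had no counts in untreated WT and was at least 1022-fold higher after treatment. Nlrc5, the class I transactivator, rose 6138-fold from 2 counts (counting interval 1699 to 50686). Of 24 class I genes, 20 rose, 3 fell and 1 was not called (median 4.76, camera adjusted p = 3.21e-171).

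Class II, GTPase and antiviral genes rose in WT as well. Ciita, the class II transactivator, rose 2480.3-fold from 1 count (counting interval 445 to 97990.5). Of 12 class II genes, 9 rose, 1 fell and 2 were not called (median 6.96, or 5.29 with genes near 0 counts at their bound, camera adjusted p = 2.57e-21). All 20 tested entries of the IFN-inducible GTPases rose (median 11.65, or 10.03 with bounds, adjusted p = 1.81e-05 with an estimated correlation), and Gm12250 makes up 2 of these entries. Tgtp1, Tgtp2, Gbp4 and Gbp10 went from no counts to at least 30003-fold, 26702-fold, 14412-fold and 10103-fold higher, and Gbp2 rose by 10.23 (SE 0.12). All 36 tested antiviral genes rose (median 5.95, adjusted p = 1.81e-05 with an estimated correlation), with the oligoadenylate synthetase-like gene Oasl2 at 9.72 (SE 0.32). Tgtp1 and Tgtp2, the Gbp genes and the H2 genes have close relatives, and reads shared between such genes could not be assigned with certainty.

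Signalling, chemokine, checkpoint, cell death and complement genes rose in WT as lists. Of 24 receptor and JAK-STAT genes, 18 rose, 3 fell and 3 were not called (median 1.29, camera adjusted p = 9.72e-51). Socs1, the feedback inhibitor of JAK kinases, rose by 5.70 (SE 0.30), Jak2 by 0.91 (SE 0.052) and Jak1 by 0.18 (SE 0.037). The receptor gene Ifngr2 fell by 0.46 on the log2 scale (SE 0.053), and Ifngr1 fell by 0.26 (SE 0.070, adjusted p = 0.00561). Ifngr1 was not called without WT untreated replicate 1 (adjusted p = 0.1003) or with DESeq2 (adjusted p = 0.0856). Of 15 chemokine and cytokine genes, 10 rose and 3 fell (median 2.60, or 2.45 with bounds, camera adjusted p = 3.91e-09). Of the T cell attractants, Cxcl10 rose by 5.89 (SE 0.096) and Cxcl9 went from no counts to at least 45.4-fold higher. Of 15 tested checkpoint genes, out of 27 listed, 8 rose and 1 fell (median 0.70, camera adjusted p = 1.23e-10). Cd274, which encodes the PD-1 ligand PD-L1, rose by 4.66 (SE 0.089), from 8.20 ± 0.281 to 208 ± 7.09 CPM. Of 23 cell death genes, 13 rose and 3 fell (median 0.35, camera adjusted p = 4.56e-07), with the inflammatory caspase gene Casp4 at 4.30 (SE 0.30). Of 8 complement genes, 7 rose and 1 fell (median 2.40, camera adjusted p = 2.08e-18).

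Proliferation genes fell in WT cells given IFN-γ. Mki67, a marker of cycling cells, fell by 0.74 on the log2 scale (SE 0.043), from 699 ± 28.3 to 419.6 ± 24.6 CPM. Of 37 cell cycle genes, 29 fell, 2 rose and 6 were not called (median −0.23, camera adjusted p = 5.58e-05, adjusted p = 0.0815 with an estimated correlation). Of 17 glycolysis genes, 12 fell and 2 rose (median −0.22, camera adjusted p = 0.0357, adjusted p = 0.536 with an estimated correlation). The glycolysis list was not past the threshold without WT IFN-γ replicate 2 (adjusted p = 0.0615). Of 16 early response genes, 8 rose and 4 fell (median 0.29, camera adjusted p = 0.0472, adjusted p = 0.363 with an estimated correlation). That list was lost without WT untreated replicate 2 (adjusted p = 0.0737), WT IFN-γ replicate 2 (0.0615) or WT IFN-γ replicate 3 (0.0754), and with a replicate block (0.0662).

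Pigment genes moved both ways in WT, 11 of 22 higher and 6 lower (median 0.052, mean −0.0012, camera adjusted p = 0.750). Mitf, a master regulator of melanocytes, rose by 0.54 (SE 0.029), the melanosome gene Pmel rose by 0.14 (SE 0.022), and the tyrosinase gene Tyr fell by 0.37 on the log2 scale (SE 0.030). The largest decreases among genes with at least 5 CPM included the lipid transporter gene Abca12 (−2.17, SE 0.080), the metalloprotease gene Adam12 (−2.13, SE 0.073), Tenm4 (−2.05, SE 0.090) and Igsf3 (−1.97, SE 0.054). Gm43590 also fell, from 32.7 ± 13.6 CPM in untreated WT to no counts, so its fold cannot be sized. Lists not past the threshold were adhesion (6 higher and 12 lower of 25, median −0.10, mean 0.059, adjusted p = 0.257), ER stress (4 and 12 of 18, 0.0724), hypoxia (2 and 6 of 15, 0.502) and p53 targets (5 and 6 of 17, 0.710). The same held for mitochondrially encoded genes (2 and 6 of 12, 0.357), nuclear oxidative phosphorylation genes (6 and 4 of 26, 0.905, a positive median of 0.019 with the test pointing down), cholesterol synthesis (2 and 7 of 18, 0.357) and dedifferentiation (6 and 2 of 10, 0.615).

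By edgeR, 3803 genes rose and 3055 fell in WT at an adjusted p under 0.05, of which 765 and 344 changed at least 2-fold. Adjusted over the list alone, counts higher and lower were 20 and 3 for class I, 9 and 1 for class II, 19 and 3 for signalling, 20 and 0 for GTPases and 36 and 0 for antiviral genes. They were 11 and 3 for chemokines, 8 and 1 for checkpoint genes, 13 and 3 for cell death, 7 and 1 for complement, 3 and 30 for the cell cycle, 2 and 13 for glycolysis and 8 and 5 for early response genes. With an estimated correlation, the lists of class I, class II, signalling, GTPase, antiviral, chemokine, checkpoint, cell death and complement genes also passed.

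In OVA cells, signalling and antigen presentation genes also rose with IFN-γ. Irf1 rose by 5.99 (SE 0.069, adjusted p = 8.35e-22). H2-K1 rose by 5.35 (SE 0.059), H2-D1 by 3.87 (SE 0.043), B2m by 3.86 (SE 0.033) and Tap1 by 7.24 (SE 0.11). Cd274 rose by 4.65 (SE 0.087), from 8.50 ± 1.54 to 213 ± 2.77 CPM (n = 2 and 3), and Cxcl10 by 5.10 (SE 0.072). Gbp2 rose by 9.81 (SE 0.099), and Tgtp1, Tgtp2, Gbp4 and Gbp10 were at least 30329.8-fold, 28940.4-fold, 13852-fold and 9802-fold higher. Nlrc5 rose by 10.35 (SE 0.39). Psmb8 rose 1696-fold from 2 counts (counting interval 469 to 14005), Ciita 842-fold from 3 counts (288 to 4083) and Cxcl9 163-fold from 1 count (28.9 to 6446).

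As lists in OVA, class I genes were 20 higher and 3 lower of 24 (median 4.57, camera adjusted p = 4.74e-159), and class II genes 9 and 1 of 12 (median 7.08, or 5.41 with bounds, camera adjusted p = 9.74e-21). All 20 GTPase entries (median 11.35, or 9.71 with bounds) and all 36 antiviral genes (median 5.23) rose, each with adjusted p = 1.81e-05 with an estimated correlation. Signalling genes were 18 higher and 4 lower of 24 (median 1.17, camera adjusted p = 7.62e-49), chemokines 11 and 3 of 15 (median 2.52, 6.52e-09) and checkpoint genes 8 and 2 of 15 (median 0.24, 1.56e-10). Cell death genes were 14 higher and 4 lower of 23 (median 0.72, camera adjusted p = 1.43e-06) and complement genes 7 and 0 of 8 (median 2.08, 7.73e-17). Socs1 rose by 5.04 (SE 0.24), Jak2 by 0.86 (SE 0.051) and Jak1 by 0.11 (SE 0.037), while Ifngr1 was at −0.30 (SE 0.070) and Ifngr2 at −0.53 (SE 0.052). Jak1 was not called without OVA untreated replicate 1 (adjusted p = 0.224), OVA IFN-γ replicate 1 (0.0657) or OVA IFN-γ replicate 2 (0.0943), or with DESeq2 (0.0553).

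Cell cycle, glycolysis and mitochondrially encoded genes fell in OVA. Mki67 fell by 0.88 on the log2 scale (SE 0.043), and 32 of 37 cell cycle genes fell with 1 higher (median −0.30, camera adjusted p = 7.92e-06, adjusted p = 0.0533 with an estimated correlation). The lactate exporter gene Slc16a3 was at −0.93 (SE 0.038) and the enolase gene Eno1 at −0.67 (SE 0.027). Of 17 glycolysis genes, 14 fell and 2 rose (median −0.33, camera adjusted p = 3.63e-04, adjusted p = 0.318 with an estimated correlation). Of 12 mitochondrially encoded genes, 10 fell and 1 rose (median −0.32, camera adjusted p = 0.0121, adjusted p = 0.445 with an estimated correlation). The share of all counts from mitochondrially encoded genes was 3.29% and 3.38% in untreated and 2.70% to 2.89% in treated OVA, against 2.98% and 3.03% in untreated and 2.88% to 2.94% in treated WT. Pigment genes were 10 higher and 9 lower of 22 (median 0.043, mean −0.016, camera adjusted p = 0.850), with Mitf at 0.48 (SE 0.029), Pmel at 0.15 (SE 0.022) and Tyr at −0.40 (SE 0.030). Abca12 (−2.24, SE 0.057), Adam12 (−2.10, SE 0.073), Tenm4 (−2.06, SE 0.094) and Igsf3 (−2.01, SE 0.056) were among the largest decreases.

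By edgeR, 4017 genes rose and 3563 fell in OVA, 821 and 433 of them at least 2-fold. Counts higher and lower adjusted over the list alone were 20 and 3 for class I, 9 and 2 for class II, 18 and 4 for signalling, 20 and 0 for GTPases, 36 and 0 for antiviral genes and 11 and 3 for chemokines. They were 8 and 2 for checkpoint genes, 14 and 4 for cell death, 7 and 0 for complement, 1 and 33 for the cell cycle, 2 and 14 for glycolysis and 1 and 10 for mitochondrially encoded genes. With an estimated correlation, class I, class II, signalling, GTPase, antiviral, chemokine, checkpoint, cell death and complement genes passed in OVA too. Across the lines, 3147 genes rose in both and 2571 fell in both, where independent lists would share 983.94 and 701.08. Both lists came from the same fit of the same genes, so they are not independent and this is not a test. A further 1135 genes were called in WT alone and 1857 in OVA alone, which is not a test of a difference. In opposite directions, 5 genes were called. Of these, in the main fit only Hmmr, singled out after its values were seen, was called for the difference of responses (−0.284, adjusted p = 0.0247), with 0.124 in WT and −0.160 in OVA. That call was lost without 7 of the 10 libraries in turn (adjusted p = 0.0602 to 0.169), and the WT one without 2 of them (0.0650 and 0.0859) or with DESeq2 (0.0889). The other 4 were called for the difference in some alternatives, mt-Co1 with no filter (3.06e-04), a replicate block (0.0458), protein-coding genes (0.0467) and without WT IFN-γ replicate 3 (0.00967). Uso1 was called with a replicate block (0.0371), and Nat8f3 (0.00869) and Sox4 (0.0343) with no filter. The opposite calls of these 4 did not hold throughout. With the DESeq2 Wald test none of them was called in either line (adjusted p = 0.0799 to 0.187). With the stricter filter mt-Co1 (0.127) and Uso1 (0.0775) were not called in WT. Each also lost a call in WT or OVA in some fits without 1 IFN-γ library. Over the 575 genes changed at least 2-fold in WT with at least 1 CPM in both untreated lines, the slope of the OVA on the WT log2 change was 0.957 and Pearson's r was 0.987. That correlation is across genes, which are not independent replicates. The genes were picked by their WT change, which can lower the slope, so the slope does not measure a weaker response in OVA.

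**Figure D1:**
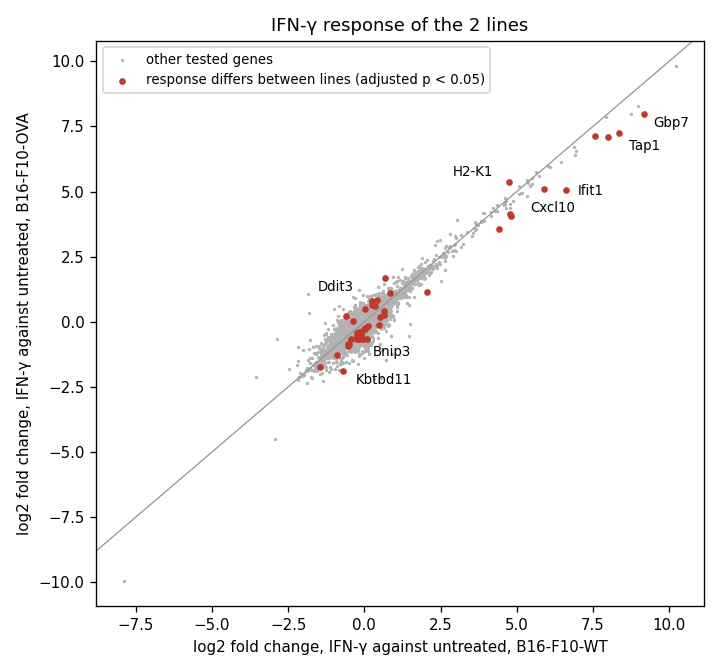
Log2 fold change with IFN-γ in WT (horizontal axis) and OVA (vertical axis) for the 12590 tested genes with a mean of at least 1 CPM in both untreated groups, where each point is a gene, red marks genes whose response differed between the lines and the line marks equal responses. H2-K1 lies above the line and Ifit1, Tap1 and Cxcl10 below it, and Gpr137b-ps at the lower left had no counts in either treated group or in WT untreated replicate 2, so its position is not a fold on either axis.

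The question of the series, whether the lines respond differently, was addressed by the difference of the responses, OVA minus WT. Kbtbd11 (ENSMUSG00000055675) differed by −1.19 log2 units (SE 0.11, adjusted p = 6.75e-05), with means of 18.9 and 5.08 CPM in untreated and treated OVA and 31.5 and 19.2 CPM in WT (n = 2 and 3). Bnip3 (ENSMUSG00000078566), a mitophagy gene induced by hypoxia, differed by −0.60 (SE 0.057, adjusted p = 6.75e-05), with 84.9 ± 0.642 and 53.8 ± 1.05 CPM in OVA and 132 ± 3.72 and 127 ± 4.34 CPM in WT. The antiviral gene Ifit1 (ENSMUSG00000034459) rose by a smaller fold in OVA (−1.56, SE 0.16, adjusted p = 6.75e-05). Its level there went from 9.74 ± 0.0670 to 324 ± 5.78 CPM, against 2.34 ± 0.732 to 229.5 ± 4.34 CPM in WT. H2-K1 rose by a larger fold in OVA (0.60, SE 0.077, adjusted p = 0.00105). Its level there went from 15.1 ± 0.327 to 616 ± 7.38 CPM, against 26.7 ± 1.61 to 718 ± 24.9 CPM in WT. Slc16a3 differed by −0.39 (SE 0.051), the receptor gene Notch1 by −0.90 (SE 0.13), the early growth response gene Egr1 by −0.58 (SE 0.066) and the stress-induced transcription factor gene Ddit3 by 0.57 (SE 0.064). These 8 genes were called in every fit that left out 1 library.

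Hypoxia, glycolysis, mitochondrially encoded and antiviral genes had lower responses in OVA as lists. Of 15 hypoxia genes, 3 were lower and 12 not called (median −0.087, camera adjusted p = 3.31e-09, adjusted p = 0.00409 with an estimated correlation). Of 17 glycolysis genes, 5 were lower (median −0.13, camera adjusted p = 3.26e-14, adjusted p = 0.0355 with an estimated correlation). Of 12 mitochondrially encoded genes, 2 were lower, mt-Nd5 (−0.43, SE 0.062) among them (median −0.22, camera adjusted p = 1.75e-14, adjusted p = 0.0305 with an estimated correlation). Of 36 antiviral genes, 6 were lower and 30 not called (median −0.28, camera adjusted p = 3.78e-11, adjusted p = 0.0226 with an estimated correlation). As a list, antiviral genes were higher in OVA than in WT both untreated and after IFN-γ. Their lower response was thus a smaller fold change from a higher untreated level, not a lower treated level. Adjusted over the list alone, counts higher and lower were 0 and 5 for hypoxia, 0 and 9 for glycolysis, 0 and 10 for mitochondrially encoded and 1 and 13 for antiviral genes.

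GTPase, cell cycle, nuclear oxidative phosphorylation and stress genes passed for a difference of response with the preset correlation and were lost with the estimated one. GTPases had 2 lower of 20 (median −0.18, camera adjusted p = 0.0183, adjusted p = 0.417 with an estimated correlation), and cell cycle genes 2 lower of 37 (median −0.043, camera adjusted p = 0.0266, adjusted p = 0.318 with an estimated correlation). Tgtp1, Tgtp2, Gbp4, Gbp9 and Gbp10 had no counts in either untreated group, so the GTPase median and test include differences that cannot be sized. Nuclear oxidative phosphorylation genes had 0 called of 26 (median 0.060, camera adjusted p = 0.00139, adjusted p = 0.510 with an estimated correlation), and stress genes 3 higher of 18 (median 0.0096, camera adjusted p = 0.0472, adjusted p = 0.502 with an estimated correlation). Counts higher and lower adjusted over the list alone were 0 and 5, 2 and 12, 0 and 0, and 3 and 5 in that order. The cell cycle list was lost without WT untreated replicate 2 (adjusted p = 0.119), WT IFN-γ replicate 1 (0.0770), OVA untreated replicate 1 (0.0761) or OVA IFN-γ replicate 1 (0.136). The stress list was lost without WT untreated replicate 1 (0.310), WT IFN-γ replicate 2 (0.125), OVA untreated replicate 1 (0.198) or OVA IFN-γ replicate 3 (0.147), and the oxidative phosphorylation list without WT untreated replicate 1 (0.0638). With fry, GTPase (0.0603), oxidative phosphorylation (0.338) and stress genes (0.306) were lost too. Class I (1 higher and 1 lower of 24, 0.379), class II (0 and 0 of 12, 0.984) and signalling genes (0 and 0 of 24, 0.635) did not pass.

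Most other genes fixed in advance were not called for a difference of response. The difference and its 95% interval were −0.045 (−0.25 to 0.16) for Irf1, −0.050 (−0.18 to 0.080) for H2-D1, 0.034 (−0.065 to 0.13) for B2m and −0.013 (−0.28 to 0.25) for Cd274. They were −0.42 (−0.75 to −0.10) for Gbp2, −0.034 (−0.24 to 0.18) for Ifngr1, −0.070 (−0.23 to 0.087) for Ifngr2, −0.074 (−0.18 to 0.036) for Jak1 and −0.050 (−0.20 to 0.10) for Jak2. Mitf differed by −0.060 (−0.15 to 0.027), Tyr by −0.026 (−0.12 to 0.063), Pmel by 0.011 (−0.056 to 0.078) and Socs1 by −0.67 (−1.48 to 0.15). Psmb8, Nlrc5, Ciita and Cxcl9 had too few untreated counts for a difference to be sized. Tap1 (−1.12, SE 0.20, adjusted p = 0.0156) and Cxcl10 (−0.79, SE 0.12, adjusted p = 0.00398) were called as rising by a smaller fold in OVA. Each started from a higher untreated level there. Summed untreated counts in WT and OVA were 54 and 121 for Tap1 and 174 and 333 for Cxcl10. Mean treated levels were not lower in OVA. In WT and OVA they were 496.3 and 500.5 CPM for Tap1 and 287.6 and 311.5 CPM for Cxcl10. Tap1 was lost without WT untreated replicate 1 (0.199), WT untreated replicate 2 (0.0735) or OVA untreated replicate 1 (0.319), and Cxcl10 without WT untreated replicate 2 (0.0752) or OVA untreated replicate 2 (0.0574).

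In total, 12 genes had a higher and 41 a lower response in OVA by edgeR, 3 and 6 of them by at least 2-fold. Of 15526 tested genes, 1657 had an unadjusted p under 0.05, a larger share than the 0.05 expected if no response differed. The total of 53 moved to 21, 23 and 22 without WT untreated replicate 1, OVA untreated replicate 1 and OVA untreated replicate 2, and to 107 without WT IFN-γ replicate 3. The 41 moved to 26 without OVA IFN-γ replicate 2. With a replicate block 165 genes were called for a difference, and 284 with no filter. An interferon response score, the mean log2 CPM over 80 entries of the class I, GTPase and antiviral lists, rose by 6.67 (SE 0.0273) in WT and 6.39 (SE 0.0185) in OVA, each with an exact two-sided permutation p = 0.1, the smallest that 10 splits allow. The difference of these responses was −0.275 (SE 0.0330) and was not tested. With the median over members in place of the mean it was −0.614, and the untreated difference 0.721 in place of 0.391. The score was 1.12 ± 0.0366 in untreated WT and 1.51 ± 0.0197 in untreated OVA (exact two-sided permutation p = 0.333, the smallest possible). After IFN-γ it was 7.78 ± 0.0149 in WT and 7.90 ± 0.0210 in OVA (exact two-sided permutation p = 0.1, the smallest possible).

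**Figure D2:**
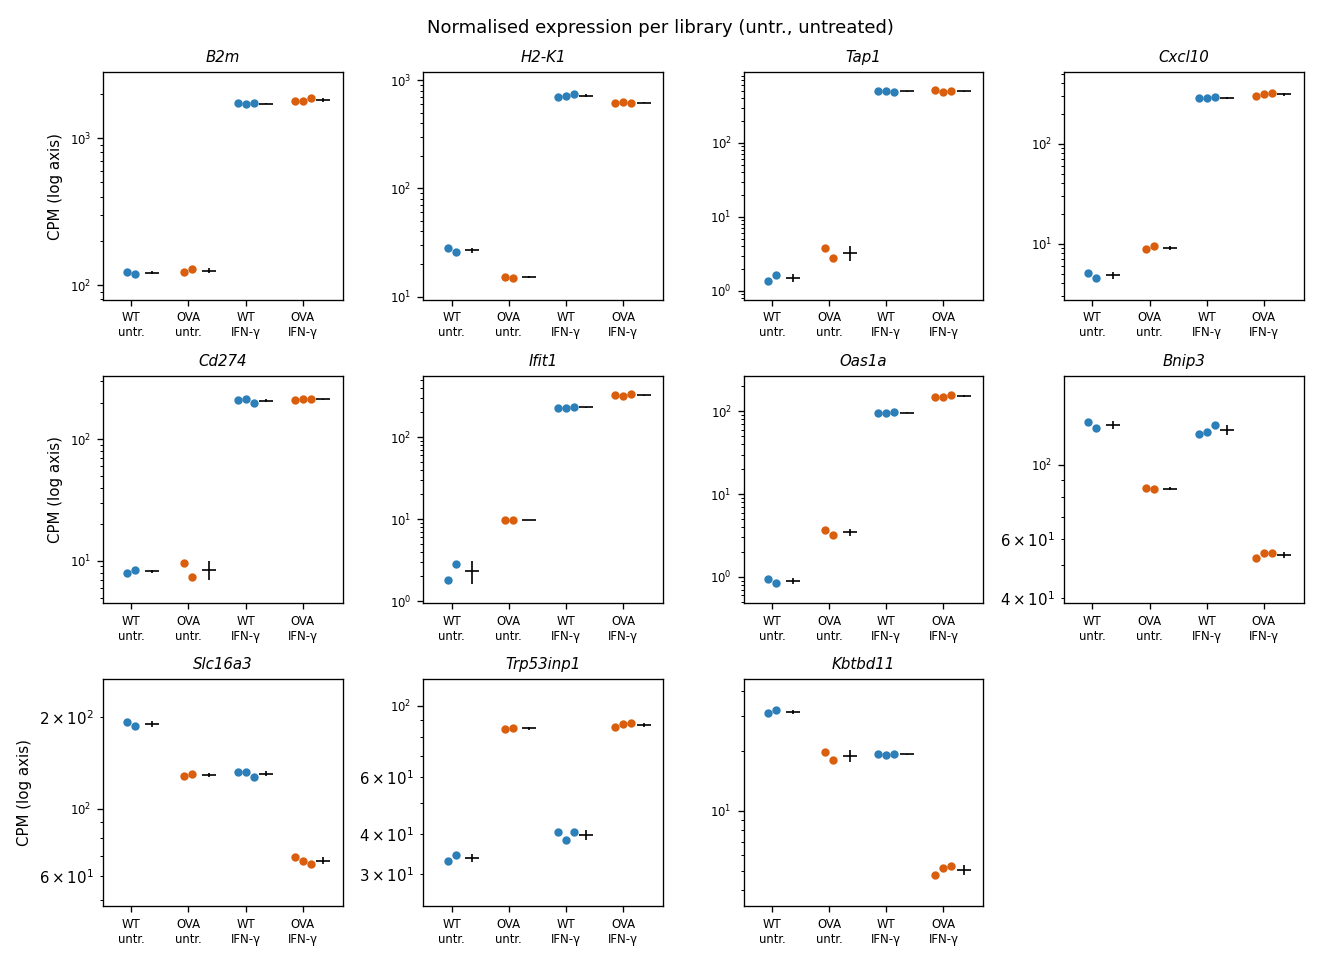
Normalised expression (CPM, log axis) of 11 genes in the 10 libraries, blue for WT and orange for OVA, where points are libraries and the bar beside them is mean ± SD. Bnip3 had 132 ± 3.72 CPM in untreated WT and 53.8 ± 1.05 CPM in treated OVA, and Ifit1 had 2.34 ± 0.732 and 9.74 ± 0.0670 CPM in untreated WT and OVA.

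Between the untreated lines, antiviral and p53 target genes were higher in OVA. Ifit1 was higher by 2.06 log2 units (SE 0.16, adjusted p = 1.15e-07, n = 2 each), with Oas1a at 1.95 (SE 0.25) and Ifit3 at 1.20 (SE 0.17). Of 36 antiviral genes, 15 were higher, 0 lower and 21 not called (median 0.54, or 0.47 with bounds, camera adjusted p = 9.20e-20, adjusted p = 0.00573 with an estimated correlation). Trp53inp1, a p53 target gene, was higher by 1.34 (SE 0.051, adjusted p = 1.09e-10), at 33.7 ± 1.01 CPM in WT and 85.0 ± 0.781 CPM in OVA. Cdkn1a, which encodes the CDK inhibitor p21, was at 1.02 (SE 0.044) and Ccng1 at 1.03 (SE 0.042). Of 17 CDK inhibitors and p53 targets, 9 were higher and 1 lower (median 0.36, camera adjusted p = 1.11e-47, adjusted p = 6.24e-05 with an estimated correlation).

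Hypoxia, glycolysis and cholesterol synthesis genes were lower in untreated OVA. Ndrg1 (−0.77, SE 0.059), the oxidoreductase gene Ero1a (−0.74, SE 0.034) and Bnip3 (−0.64, SE 0.043) were among 10 of 15 hypoxia genes that were lower, with 0 higher (median −0.29, camera adjusted p = 2.95e-34, adjusted p = 1.47e-04 with an estimated correlation). Of 17 glycolysis genes, 16 were lower and 1 not called (median −0.24, camera adjusted p = 3.30e-38, adjusted p = 0.00422 with an estimated correlation), such as Slc16a3 (−0.56, SE 0.038) and the hexokinase gene Hk2 (−0.38, SE 0.038). Slc2a1 and Pdk1 belong to both lists. Of 18 cholesterol synthesis genes, 6 were lower and 12 not called (median −0.13, camera adjusted p = 2.82e-09, adjusted p = 0.0165 with an estimated correlation), including Insig1 (−0.25, SE 0.033). Adjusted over the list alone, counts higher and lower were 23 and 0 for antiviral genes, 11 and 1 for p53 targets, 0 and 12 for hypoxia, 0 and 17 for glycolysis and 0 and 11 for cholesterol synthesis.

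Among genes fixed in advance, H2-K1 was lower in untreated OVA (−0.82, SE 0.071, adjusted p = 1.34e-06). Cxcl10 (0.90, SE 0.12, adjusted p = 1.03e-04) and Tap1 (1.13, SE 0.20, adjusted p = 0.00170) were higher. Tap1 was not called without OVA untreated replicate 1 (adjusted p = 0.0692). Irf1 (−0.042, SE 0.093), H2-D1 (−0.0029, SE 0.053), B2m (0.049, SE 0.039), Cd274 (0.050, SE 0.12), Gbp2 (0.49, SE 0.15) and Socs1 (0.58, SE 0.38) were not called. Jak1 (−0.032), Jak2 (0.051), Ifngr1 (0.048), Ifngr2 (0.10), Mitf (0.041), Tyr (0.037) and Pmel (0.063) were not called either, nor were Psmb8, Nlrc5, Ciita and Cxcl9, which were near 0 counts.

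Further lists passed between the untreated lines with the preset correlation and not with the estimated one. GTPases were 3 higher of 20 (median 0.40, or 0.14 with bounds, camera adjusted p = 0.0141, adjusted p = 0.402 with an estimated correlation). Pigment genes were 4 higher and 2 lower of 22 (median 0.058, camera adjusted p = 0.00111, adjusted p = 0.318 with an estimated correlation), with the channel gene Trpm1 at 0.70 (SE 0.037). Dedifferentiation genes were 2 lower of 10 (median −0.048, camera adjusted p = 9.20e-04, adjusted p = 0.0923 with an estimated correlation). Mitochondrially encoded genes were 5 higher of 12 (median 0.14, camera adjusted p = 3.49e-05, adjusted p = 0.215 with an estimated correlation). Cell cycle genes were 6 higher and 2 lower of 37 (median 0.027, camera adjusted p = 0.0472, adjusted p = 0.367 with an estimated correlation). Cell death genes were 4 higher and 1 lower of 23 (median 0.075, camera adjusted p = 0.0404, adjusted p = 0.124 with an estimated correlation), and nuclear oxidative phosphorylation genes had 0 called of 26 (median −0.048, camera adjusted p = 0.0286, adjusted p = 0.663 with an estimated correlation). Counts higher and lower adjusted over the list alone were 6 and 0 for GTPases, 9 and 2 for pigment genes, 0 and 3 for dedifferentiation, 9 and 0 for mitochondrially encoded genes, 9 and 2 for the cell cycle, 5 and 1 for cell death and 0 and 2 for nuclear oxidative phosphorylation. The cell cycle list was lost without WT untreated replicate 2 (0.111), WT IFN-γ replicate 1 (0.0515) or 2 (0.0626), OVA untreated replicate 1 (0.107) or OVA IFN-γ replicate 1 (0.0502), and with DESeq2 size factors (0.0667). The cell death list was lost without WT untreated replicate 1 (0.0912) or OVA untreated replicate 2 (0.0665), and the oxidative phosphorylation list without WT untreated replicate 1 (0.308) or OVA untreated replicate 1 (0.0879).

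Genes most increased in untreated OVA with at least 5 CPM included Inka2 (2.01, SE 0.20), the receptor phosphatase gene Ptprd (1.54, SE 0.20) and Abca12 (1.46, SE 0.058). The most decreased included the glycogen phosphorylase gene Pygl (−1.17, SE 0.15), Aire (−1.09, SE 0.14) and Selenbp1 (−0.92, SE 0.072). The largest decrease was that of Gm43590, with 32.7 ± 13.6 CPM in untreated WT and no counts in any other group, so its fold cannot be sized. It is among the carriers of Gm42860 sequence described below, whose reads may be shared between genes. By edgeR, 463 genes were higher and 396 lower, 43 and 20 of them by at least 2-fold. The total of 859 moved to 350, 364, 378 and 350 without WT untreated replicates 1 and 2 and OVA untreated replicates 1 and 2.

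**Figure D3:**
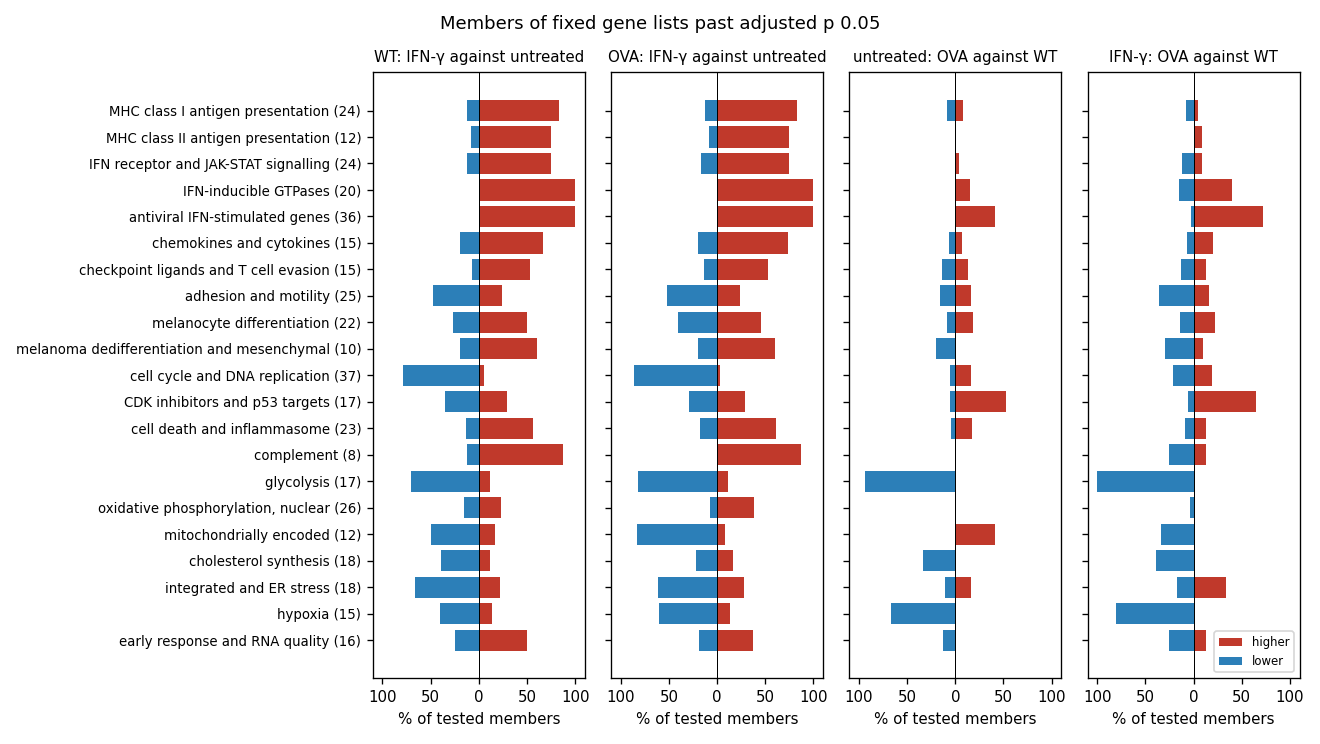
Share of tested members (horizontal axis, %) called higher (red) or lower (blue) at an adjusted p under 0.05 for gene lists fixed in advance (vertical axis), in 4 comparisons. All 17 glycolysis genes were lower in OVA than in WT after IFN-γ, and all 36 antiviral genes rose with IFN-γ in each line.

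After IFN-γ, hypoxia and glycolysis genes were lower in OVA than in WT, and antiviral and p53 target genes were higher. The log2 difference for Bnip3 was −1.24 (SE 0.037, adjusted p = 3.24e-12, n = 3 each), and 12 of 15 hypoxia genes were lower with 0 higher (median −0.55, camera adjusted p = 6.74e-56, adjusted p = 5.57e-05 with an estimated correlation). All 17 glycolysis genes were lower (median −0.34, camera adjusted p = 2.79e-74, adjusted p = 9.45e-04 with an estimated correlation), with Slc16a3 at −0.95 (SE 0.034) and Hk2 at −0.70 (SE 0.031). Usp18, of the signalling list, was higher by 0.82 (SE 0.035) and the antiviral gene Oas1a by 0.66 (SE 0.036). Of 36 antiviral genes, 26 were higher and 1 lower (median 0.25, camera adjusted p = 8.69e-44, adjusted p = 0.00117 with an estimated correlation). Of 17 CDK inhibitors and p53 targets, 11 were higher and 1 lower (median 0.34, camera adjusted p = 2.05e-33, adjusted p = 1.47e-04 with an estimated correlation), with Trp53inp1 at 1.13 (SE 0.040) and Cdkn1a at 0.89 (SE 0.036).

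Of 24 class I genes, 1 was higher and 2 lower in treated OVA than in treated WT (median −0.010, camera adjusted p = 0.736), with H2-K1 at −0.22 (SE 0.029, adjusted p = 7.44e-05). B2m (0.083, SE 0.027, adjusted p = 0.0466), Cxcl10 (0.12, SE 0.029, adjusted p = 0.0146), Pmel (0.074, SE 0.020, adjusted p = 0.0193) and Jak1 (−0.11, SE 0.033, adjusted p = 0.0368) were called. Jak1 was not called without each library except WT IFN-γ replicate 3 (adjusted p = 0.0523 to 0.174) or with DESeq2 (0.106). B2m was not called without WT untreated replicate 1 (0.0512) or 2 (0.0509), WT IFN-γ replicate 1 (0.0867) or 2 (0.166), or OVA IFN-γ replicate 2 (0.0673) or 3 (0.166), or with DESeq2 size factors (0.0519). Cxcl10 was not called without WT IFN-γ replicate 1 (0.0522) or 2 (0.0677) or OVA IFN-γ replicate 3 (0.0586), nor Pmel without WT IFN-γ replicate 2 (0.0724) or OVA IFN-γ replicate 3 (0.0503). Tap1 (0.012, SE 0.030), H2-D1 (−0.053, SE 0.030), Cd274 (0.037, SE 0.036), Gbp2 (0.061, SE 0.028) and Irf1 (−0.087, SE 0.030) were not called, though Irf1 was with a replicate block (adjusted p = 0.0137). Nlrc5 (−0.054), Ciita (−0.0058), Cxcl9 (0.22), Socs1 (−0.094), Jak2 (0.00098), Ifngr1 (0.014), Ifngr2 (0.032), Mitf (−0.019) and Tyr (0.010) were not called. Psmb8 (0.12, adjusted p = 0.0612) was called without WT IFN-γ replicate 3 (0.0199) and with a replicate block (0.0393).

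Adhesion, cholesterol, dedifferentiation, pigment and mitochondrially encoded genes passed between the treated lines with the preset correlation and not with the estimated one. Adhesion genes were 4 higher and 9 lower of 25 (median −0.068, camera adjusted p = 0.00307, adjusted p = 0.0674 with an estimated correlation), with the integrin gene Itgb3 at −0.65 (SE 0.044). Cholesterol synthesis genes were 0 higher and 7 lower of 18 (median −0.092, camera adjusted p = 3.08e-04, adjusted p = 0.0923 with an estimated correlation). Dedifferentiation genes were 1 higher and 3 lower of 10 (median −0.080, camera adjusted p = 0.00282, adjusted p = 0.124 with an estimated correlation), with the collagen crosslinking gene Loxl2 at −1.07 (SE 0.052). Pigment genes were 5 higher and 3 lower of 22 (median 0.013, camera adjusted p = 0.0372, adjusted p = 0.510 with an estimated correlation), and were lost without WT IFN-γ replicate 2 (0.0795) or OVA IFN-γ replicate 3 (0.0916). Mitochondrially encoded genes were 0 higher and 4 lower of 12 (median −0.063, camera adjusted p = 0.0308, adjusted p = 0.510 with an estimated correlation). They were lost without WT untreated replicate 1 (0.0620) or 2 (0.0584), WT IFN-γ replicate 2 (0.0615), OVA untreated replicate 1 (0.0742) or 2 (0.0731) or OVA IFN-γ replicate 1 (0.397).

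Genes most increased in treated OVA with at least 5 CPM included Inka2 (1.67, SE 0.17), the potassium channel gene Kcnj13 (1.44, SE 0.11) and Abca12 (1.39, SE 0.079). The most decreased included Kbtbd11 (−1.92, SE 0.084), Aire (−1.67, SE 0.14), Selenbp1 (−1.15, SE 0.067) and Pygl (−0.99, SE 0.13). By edgeR, 988 genes were higher and 1241 lower, 64 and 49 of them by at least 2-fold. The 988 moved to 586 without WT IFN-γ replicate 2, and the 1241 to 795 without OVA IFN-γ replicate 3. Adjusted over the list alone, counts higher and lower were 0 and 12 for hypoxia, 0 and 17 for glycolysis, 28 and 1 for antiviral genes and 12 and 2 for p53 targets. They were 4 and 12 for adhesion, 1 and 10 for cholesterol synthesis, 2 and 5 for dedifferentiation, 7 and 6 for pigment genes and 0 and 6 for mitochondrially encoded genes.

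Markers of other cell types were low. The highest level of any marker in any library was 9.41 CPM for the macrophage gene Mpeg1, 4.01 CPM for the T cell kinase gene Lck, 3.72 CPM for the fibroblast gene Col1a2 and 1.52 CPM for the epithelial gene Cdh1. With camera none of these lists passed in any of the 5 comparisons (in WT, adjusted p = 0.726 for 1 T cell, 0.508 for 4 macrophage, 0.736 for 4 fibroblast and 0.961 for 1 epithelial gene or genes tested). With fry the T cell (0.000795), macrophage (0.000399) and fibroblast lists (0.0381) passed in WT, and the T cell (0.00101) and macrophage lists (0.000430) in OVA. Single markers did rise with IFN-γ. Mpeg1 had no counts in either untreated line and was at least 103-fold higher in WT and 112-fold in OVA after treatment, and Lck rose by 1.46 (SE 0.24) and 1.26 (SE 0.22). The macrophage gene Cd68 was called in WT (0.81, SE 0.24, adjusted p = 0.0110) and OVA (0.70, SE 0.25, adjusted p = 0.0256). Its call was lost in WT without WT untreated replicate 1 (0.184) or WT IFN-γ replicate 2 (0.0540), in OVA without OVA untreated replicate 2 (0.217) or OVA IFN-γ replicate 2 (0.0745), and in both with DESeq2 (0.0603 and 0.107). The leukocyte gene Ptprc and the T cell gene Cd3e had 0 counts. The ribosomal RNA gene Rn18s-rs5 took 0.146% of the counts of WT untreated replicate 1 and 0.191% of OVA untreated replicate 1, against 0.331% to 0.459% in the other 8 libraries.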

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

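The test of carry-over from treated libraries was chosen only after the result was seen. A test of the difference between the responses of the lines picked out 53 genes and, with the preset correlation of camera, 8 lists, of which 4 passed with an estimated correlation. Among those called without each library in turn, the difference OVA minus WT was −1.19 for Kbtbd11, −0.60 for Bnip3, −1.56 for Ifit1, 0.57 for Ddit3, −0.58 for Egr1, 0.43 for the noncoding RNA Neat1, 0.60 for H2-K1, 0.46 for Nr4a3, −0.39 for Slc16a3, −0.90 for Notch1 and −0.43 for mt-Nd5. The total of 53 moved to 21, 23 and 22 without WT untreated replicate 1, OVA untreated replicate 1 and OVA untreated replicate 2, and to 107 without WT IFN-γ replicate 3.

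Other genes lost the call without some libraries, given here with the adjusted p. Oas1g (−2.21) was lost without WT untreated replicate 1 (0.0793), Thbs1 (−0.87) without WT untreated replicate 1 (0.0672) or OVA untreated replicate 2 (0.0508), Cxcl10 (−0.79) without WT untreated replicate 2 (0.0752) or OVA untreated replicate 2 (0.0574) and Hk2 (−0.33) without WT untreated replicate 1 (0.0602) or OVA untreated replicate 1 (0.0644). Atp6-ps (0.82) was lost without WT untreated replicate 2 (0.0714), OVA untreated replicate 1 (0.0834) or OVA untreated replicate 2 (0.0531), and Eno1 (−0.22) without WT untreated replicate 2 (0.117), OVA untreated replicate 1 (0.0721) or OVA untreated replicate 2 (0.0989). The difference for mt-Nd6 (−0.41) was lost without WT untreated replicate 1 (0.0990), OVA untreated replicate 1 (0.0811) or OVA untreated replicate 2 (0.0868), and that for Tap1 (−1.12) without WT untreated replicate 1 (0.199), WT untreated replicate 2 (0.0735) or OVA untreated replicate 1 (0.319). Gbp7 (−1.17) was lost without WT untreated replicate 2 (0.252), OVA untreated replicate 1 (0.240) or OVA untreated replicate 2 (0.0508), and Chac1 (0.40) without WT untreated replicate 1 (0.163), WT IFN-γ replicate 2 (0.0541), OVA untreated replicate 1 (0.138) or OVA untreated replicate 2 (0.0872). Oas1a (−1.29) was lost without WT untreated replicate 1 (0.151), WT untreated replicate 2 (0.202), OVA untreated replicate 1 (0.174) or OVA untreated replicate 2 (0.0531), and Ifit3 (−0.91) without WT untreated replicate 1 (0.270), WT untreated replicate 2 (0.173), OVA untreated replicate 1 (0.1004) or OVA untreated replicate 2 (0.193). Trib3 (0.38) was lost without WT untreated replicate 1 (0.193), WT IFN-γ replicate 2 (0.0589), OVA untreated replicate 1 (0.193), OVA untreated replicate 2 (0.0891) or OVA IFN-γ replicate 1 (0.0602), and Irgm1 (−0.44) without WT untreated replicate 1 (0.0672), WT untreated replicate 2 (0.252), OVA untreated replicate 1 (0.228), OVA untreated replicate 2 (0.0868) or OVA IFN-γ replicate 2 (0.0522). P4ha2 (−0.36) was lost without each library except WT IFN-γ replicate 3 and OVA IFN-γ replicate 3 (0.0534 to 0.145), and Pdk1 (−0.30) without each library except WT IFN-γ replicate 1, WT IFN-γ replicate 3 and OVA IFN-γ replicate 3 (0.0664 to 0.226). Txnip (0.26) was lost without each library except WT untreated replicate 2, WT IFN-γ replicate 3 and OVA IFN-γ replicate 3 (0.0593 to 0.249), and Plk1 (−0.27) without each library except WT IFN-γ replicate 3 and OVA IFN-γ replicate 3 (0.0790 to 0.293). Ccna2 (−0.22) was lost without each library except WT IFN-γ replicate 3 (0.0571 to 0.218), Gm42863 (1.01) without each library except WT IFN-γ replicate 3 and OVA IFN-γ replicate 3 (0.0664 to 0.227), and Gabarapl1 (0.26) without each library except WT IFN-γ replicate 3 and OVA IFN-γ replicate 3 (0.0942 to 0.241).

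The lists had median differences of −0.18 for GTPases, −0.28 for antiviral genes, −0.043 for the cell cycle, −0.13 for glycolysis, 0.060 for nuclear oxidative phosphorylation, −0.22 for mitochondrially encoded genes, 0.0096 for stress and −0.087 for hypoxia. The GTPase median includes genes with no counts in either untreated group. With an estimated correlation GTPases (adjusted p = 0.417), the cell cycle (0.318), oxidative phosphorylation (0.510) and stress (0.502) were lost, and with fry GTPases (0.0603), oxidative phosphorylation (0.338) and stress (0.306). The cell cycle list was lost without WT untreated replicate 2 (0.119), WT IFN-γ replicate 1 (0.0770), OVA untreated replicate 1 (0.0761) or OVA IFN-γ replicate 1 (0.136), the stress list without WT untreated replicate 1 (0.310), WT IFN-γ replicate 2 (0.125), OVA untreated replicate 1 (0.198) or OVA IFN-γ replicate 3 (0.147) and the oxidative phosphorylation list without WT untreated replicate 1 (0.0638).

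Antiviral genes were higher in untreated OVA. Carry-over from treated libraries would bring every strongly induced gene, but 16 genes silent in untreated WT and strong in treated OVA reached a median of 0.00254 and at most 0.266 of the level it predicts. After correction for GC content and length the list median was 0.534, against 0.545 before, which argues against that bias as the whole cause. The vector, the passage history of the line or its culture may explain the difference, and none of these was tested.

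Hypoxia and glycolysis genes were lower in OVA. Between untreated lines, correction for GC content and length gave a median of −0.280 for the 30 genes of both lists, against −0.261 before. It gave −0.412 against −0.401 between treated lines and −0.105 against −0.107 for the difference of responses. Of 10000 random lists matched on expression, the lowest median was −0.0609 between untreated and −0.120 between treated lines, which argues against a trend of abundant genes there. For the difference of responses the lowest was −0.109, and 2 of the 10000 were as low as the median seen. Cell density, oxygen or medium at harvest may differ between the lines and stays open, as does a property of the line, and neither was tested.

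The 6 treated libraries make 10 splits, too few for a share under 0.05. The real split gave 2229 genes, as many in 1 of the 10 splits, and the highest of the others gave 1. Each other split put libraries of both lines in both groups. Any difference between the lines then added to the spread within groups, so the low counts there do not bear on chance.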

How the results depend on the processing

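The protein-coding alternative by GENCODE M21 was chosen only after the data were seen. For every cause below that the construction of the alternative does not show, the cause was not tested. With limma-voom, DESeq2 size factors, the stricter filter and protein-coding genes, the counts of genes stayed within 1.5 times those reported. Of genes called between untreated lines, 53.9% were higher in OVA in the main fit. That share was 44.7% with the stricter filter, 46.2% with protein-coding genes and 47.4% with only the groups compared. Which direction held more genes there thus depended on the processing.

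At least 2-fold changes, a smaller class by construction, numbered 765 higher and 344 lower in WT, 821 and 433 in OVA, 3 and 6 for the difference of responses, 43 and 20 between untreated and 64 and 49 between treated lines. At an adjusted p under 0.01 the last 3 were 6 and 15, 200 and 181, and 444 and 655. The difference of responses had 79 and 205 genes with no filter and 26 and 139 with a replicate block. The DESeq2 Wald test gave 244 and 215 genes between untreated and 500.0 and 772 between treated lines. With only the groups compared, 614 genes were lower in untreated OVA. Fry passed 23 lists in WT and 22 in OVA, and an estimated correlation passed 4 for the difference of responses, 5 between untreated and 4 between treated lines.

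With a prior count of 0.5 the score changed by 7.11 in WT and 6.77 in OVA, with a difference of −0.343 and an untreated difference of 0.459. With the median over members these were 7.33, 6.72, −0.614 and 0.721.

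With each library left out in turn, a lone untreated sample is assumed to vary like the other groups. The difference of responses then had 7 to 25 genes higher and 14 to 82 lower, the lowest without WT untreated replicate 1 and the highest without WT IFN-γ replicate 3. Between untreated lines there were 187 to 543 higher and 160 to 469 lower, and between treated lines 586 to 1124 and 795 to 1284. The score response in WT ran from 6.65 to 6.70, its difference from −0.299 to −0.249 and the untreated difference from 0.367 to 0.418.

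Signs that changed when 1 library was left out belonged to values that were not called. For the difference of responses, Irf1 ran from −0.096 to 0.0053, Ifngr1 from −0.098 to 0.028, H2-D1 from −0.13 to 0.028, B2m from −0.0028 to 0.072, Cd274 from −0.19 to 0.18, Cxcl9 from −2.94 to 0.22 and Pmel from −0.0036 to 0.026. Between untreated lines, Irf1 ran from −0.091 to 0.011, Ifngr1 from −0.013 to 0.11, H2-D1 from −0.079 to 0.081 and Cd274 from −0.14 to 0.23. Between treated lines, Ifngr1 ran from −0.018 to 0.056, Jak2 from −0.018 to 0.044, Tap1 from −0.0035 to 0.023, Ciita from −0.028 to 0.036 and Tyr from −0.0036 to 0.036.

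Of 489 results for named genes, 47 lost and 1 gained the call with the DESeq2 Wald test, 3 lost it with DESeq2 size factors, and 3 lost and 3 gained it with a replicate block. Leaving out libraries lost 330 calls and gained 2, and 24 results changed sign. The other 4534 results kept their status, which includes results not called either time. Whether replicate numbers pair the libraries could not be settled. The 13 same-numbered pairs had correlations of −0.0639 to 0.162, with 2 of them over 0.1. For 6 libraries the best correlation with another group was with a library of the same number. Not run was the choice of protein-coding genes by a biotype in the table, which gives none, and the fit with only the groups compared gives no difference of responses.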

Other observations

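No test in this part was chosen only after its result was seen. Abundant transcripts that share sequence with Gm42860 were lower after IFN-γ. Noct, Gm42860 and Gm47652 together took 2.08% to 2.13% of the counts of untreated and 0.777% to 0.825% of treated libraries, and were singled out after their values were seen. The sequence of Gm42860 matched Noct at 97.6% identity over 3984 bases, and Gm47652 at 94.9% over only 393 bases. Carriers were genes matching Gm42860 over at least 300 bases at 90% identity or more, at any place along it. A stretch common to all carriers was not shown. Among 22 other tested carriers, 16 were lower and 2 higher in WT (median −0.967). The share lower was 72.7%, against 20.4% of other genes (two-sided Fisher's exact p = 1.95e-07). In OVA 14 of 22 were lower and 2 higher, with 63.6% against 23.7% lower (two-sided Fisher's exact p = 7.89e-05). Genes that share reads are not independent, so these p-values can overstate the evidence. Reads shared between annotated genes may explain part of the decrease, and the level of Noct itself cannot be separated from such reads here.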
